A study of Arabidopsis thaliana with 24 samples.

How the data were processed

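Seeds of 8 Arabidopsis thaliana genotypes, 3 wild types and 5 mutants, were collected at 15, 17 and 21 days after flowering (DAF). Per the labels, samples were collected in triplicate, RNA was pooled to 1 sample per genotype and day, amplified by in vitro transcription and sequenced as barcoded SOLiD libraries. The deposited table of counts holds raw counts of 33597 loci in 24 columns, which the authors made against TAIR10 with an aligner and counter that the labels do not name. The deposited table of normalized signal was made by the authors with edgeR, version not given. In it each column is the count column times 1 constant, with factors relative to counts per library of 0.523 to 1.99, and it holds the 22010 loci with a total of 3 or more counts. The lec2-1 columns of 15 and 17 DAF are identical at all loci, so that library entered once with a day between the pair, which left 23 distinct libraries where the plan had counted 24. No other pair of columns was identical.

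Counts were analysed in R 4.3.3 with edgeR 4.0.16. Loci were filtered by filterByExpr (minimum count 10), libraries scaled by TMM (factors 0.486 to 1.92), and quasi-likelihood models with a term per genotype and per day fitted over all libraries, which gave 16085 tested genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Contrasts were each mutant against its own wild type, and the mean of lec1-1 against lec2-1 and abi3-5 against abi3-1, called the contrast of intolerant and tolerant mutants. A further model compared 21 with 15 DAF in the wild types, and another the slope over days of intolerant mutants and wild types. Because each genotype and day is 1 library, the days are the repeats, and a change present on 1 day only has little power. The SE rests on the spread between days of a genotype after the shared effect of the day. This spread is estimated per gene over all libraries of the model, not over those of the 2 genotypes compared alone. The core is the set of genes called in the same direction in lec1-1, abi3-5, fus3-3 and the contrast of intolerant and tolerant mutants. The labels of abi3-1 give an intolerant phenotype and the series design a tolerant one, and the design was followed.

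Gene lists were written before the data were examined: 20 lists of 326 loci, of seed storage proteins, oil body proteins, oil and fatty acid synthesis, LEA proteins, heat shock proteins, raffinose family and inositol synthesis, ABA synthesis and signalling, antioxidants, chlorophyll breakdown, photosynthesis, germination, cell cycle, shoot apex, seed coat flavonoids and mucilage, silique wall, endosperm, other seed transcription factors, targeted regulators and reference genes. Lists were tested by camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over all lists and comparisons, and again with an estimated correlation and by fry. Genes named are the targeted regulators, for each comparison the 6 higher and 6 lower called genes with the largest change, the same direction at all days and a mean of at least 20 counts, up to 4 members with the smallest adjusted p per list described, and the other seed transcription factors of the core. Other genes named as members of the core were chosen after their values were seen.

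A fold against a group with 0 counts is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts the ratio of counts is given with its 95% interval, which covers counting error only. Levels are normalized CPM, with a pseudocount of 2 for log2 levels of lists. Library totals ran from 1670355 to 6531673 counts. On simulated data 47.8% of genes changed 4-fold were recovered in the comparison of lec1-1, 28.4% in that of lec2-1, 49.3% in that of fus3-3 and 86.6% in the contrast of intolerant and tolerant mutants. Of genes changed 2-fold, 5.97, 0, 4.48 and 13.4% were recovered in these. In all simulations the changed genes had a mean of at least 20 counts, and all other genes had the same level in every library. The shares therefore do not stand for all tested genes.

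Alternatives tried were other scalings (RLE, upper quartile, library totals), no filter, DESeq2 1.42.0, limma-trend on the deposited signal, a robust fit, models without the day, with a day effect per ecotype or fitted per ecotype, a minimum change of 2-fold, the pair lec1-1 and lec2-1 alone, and each library and each day left out. Those that exchange or leave out the Col-0 libraries labelled 17 and 21 DAF, that use Ws and Ler alone, or that place the doubled lec2-1 library differently were added after the data were seen. Where leaving out libraries leaves lec2-1 or Col-0 with 1 library, that library is assumed to vary like the other groups.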

Results

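RNA of developing Arabidopsis thaliana seeds was sequenced in 8 genotypes at 15, 17 and 21 days after flowering (DAF). The genotypes were the 3 wild types Ws, Ler and Col-0 and 5 mutants of the regulators LEC1, LEC2, FUS3 and ABI3, which control seed maturation. The mutants lec1-1 and lec2-1 are in Ws, abi3-5 and abi3-1 in Ler, and fus3-3 in Col-0. According to the series design, seeds of lec1-1, abi3-5 and fus3-3 do not survive drying, and those of lec2-1, abi3-1 and the wild types do. The sample labels of abi3-1 call it intolerant, and the series design was followed. Each genotype and day is 1 library made from pooled RNA, so there are no replicate libraries of 1 genotype and day, and the 3 days served as the repeats of each genotype. The lec2-1 columns of 15 and 17 DAF were identical at every locus, so they were counted as 1 library and 23 distinct libraries remained. Library totals ran from 1670355 counts in Col-0 at 17 DAF to 6531673 in fus3-3 at 17 DAF.

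Seed storage protein genes took 62.5, 62.3 and 58.7% of all counts in Ws, Ler and Col-0 at 15 DAF, and 13.7, 19.4 and 21.2% in lec1-1, abi3-5 and fus3-3. In lec2-1 and abi3-1 they took 41.1 and 56.2%. The cruciferin gene CRC was the most abundant transcript of every library but Ws at 21 DAF, where the dehydrin gene RAB18 led with 7.19%. Plastid-encoded transcripts took 0.0305 to 0.0499% of the counts of the Ws libraries, 1.04 to 1.48% in lec1-1, and 0.206 and 0.341% in lec2-1. They took 0.0474 to 0.0987% in Ler, 0.243 to 0.437% in abi3-5 and 0.0452 to 0.139% in abi3-1. In Col-0 they took 0.0653 to 0.121%, and in fus3-3 0.434 to 0.923%. Because a few genes took most of the counts, all changes are given after TMM scaling. With library totals the median of all tested genes moved to 1.21 in lec1-1, 0.66 in lec2-1, 1.49 in abi3-5, 0.29 in abi3-1, 1.14 in fus3-3 and 0.83 in the contrast of intolerant and tolerant mutants, on the log2 scale.

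The first comparison asked what changes in wild type seeds between 15 and 21 DAF. Over Ws, Ler and Col-0 edgeR called 0 of 11463 genes, with 2205 at an unadjusted p under 0.05 and 619 called by DESeq2. The Col-0 libraries labelled 17 and 21 DAF stood apart. Across genes the correlation of the one labelled 17 DAF was 0.917 with Ws and 0.911 with Ler at 21 DAF, against 0.832 and 0.708 at 17 DAF (genes are not independent replicates). That of the one labelled 21 DAF was 0.784 and 0.805 with Ws and Ler at 21 DAF, against 0.888 and 0.833 at 17 and 0.885 and 0.856 at 15 DAF. Without the Col-0 library labelled 17 DAF edgeR called 1641 genes, and without the one labelled 21 DAF it called 1744. With both left out, which leaves Col-0 with 1 library, the count was 2972, and with their days exchanged it was 4060.

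In Ws and Ler alone, a choice made after seeing the data, 1915 of 9815 genes changed from 15 to 21 DAF, 645 higher and 1270 lower, 1913 of them the same way in both. Of 33 genes of late embryogenesis abundant (LEA) proteins, which accumulate before drying, 16 rose, 3 fell and 14 did not pass (21 and 4 adjusted over the list alone), with a list median of 1.94 (adjusted p = 1.23e-09 by camera, and adjusted p = 0.536 with an estimated correlation). M17 rose by a log2 fold change of 7.07 (SE 0.69, n = 2 libraries per day, as for all genes of this paragraph), M10 by 6.56 (SE 0.86) and ATECP31 by 5.65 (SE 0.77). Among heat shock protein genes, which code for chaperones, 5 of 11 rose and 1 fell, as did 5 and 1 adjusted over the list alone. HSP17.6C rose by 6.70 (SE 0.89), and the list median was 0.96 (adjusted p = 0.0274, and adjusted p = 0.536 with an estimated correlation). The galactinol synthase gene GOLS2 rose by 4.33 (SE 0.54), the malate synthase gene MLS by 3.21 (SE 0.59), the transcription factor gene ABI5 by 2.64 (SE 0.45) and the defensin-like gene LCR67 by 7.62 (SE 0.98). Oil and fatty acid synthesis fell: 17 of 21 genes passed, 17 also adjusted over the list alone, with a median of -4.06. FAE1, the elongase of very long chain fatty acids, fell by 7.81 (SE 0.63), and KAS1, an enzyme of fatty acid chain growth, fell by 4.82 (SE 0.51). Photosynthesis genes fell in 13 of 20 cases (16 adjusted over the list alone, median -2.62), among them LHCA3 at -4.63 (SE 0.66). Storage protein genes fell in 6 of 13 cases (8 adjusted over the list alone, median -2.93), among them SESA2 at -5.96 (SE 0.94), a tandem paralog of other albumin genes whose reads may be shared. The adjusted p values of these 3 lists were 4.41e-15, 5.39e-06 and 5.39e-06, each with adjusted p = 0.536 with an estimated correlation.

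The comparison of lec1-1 with Ws asked which genes depend on LEC1, a regulator of embryo maturation. Genes of seed reserves were lower in lec1-1. Of 13 storage protein genes 8 fell and 5 did not pass (9 fell adjusted over the list alone), with a median log2 fold change of -2.94. The cruciferin gene CRB (AT1G03880) fell by 5.52 (SE 1.11, n = 3 libraries per genotype, as for all genes of this comparison), the albumin gene SESA5 fell by 3.97 (SE 0.81) and the vicilin-like gene VCL22 fell by 2.94 (SE 0.69). Of 8 genes of oil body proteins, which coat the lipid stores, 5 fell (6 adjusted over the list alone, median -2.18), among them SEIPIN1 at -2.08 (SE 0.35). The adjusted p values were 2.34e-07 and 0.000214, with adjusted p = 0.283 and adjusted p = 0.357 with an estimated correlation. LEA genes moved both ways, 11 of 40 lower and 4 higher (14 and 5 adjusted over the list alone, median -1.50, adjusted p = 0.026, and adjusted p = 0.666 with an estimated correlation). With library totals 9 were higher and 3 lower, and the median was -0.23. SAG21 rose by 5.86 (SE 0.64), DI21 by 4.80 (SE 0.69), the dehydrin gene AT1G54410 by 4.04 (SE 0.77) and AT2G44060 by 3.54 (SE 0.62). Of 17 other seed transcription factors 5 fell and 1 rose (6 and 1 adjusted over the list alone), with a median of -1.18 that was 0.01 with library totals (adjusted p = 0.00818, and adjusted p = 0.32 with an estimated correlation). With library totals 6 storage and 2 oil body genes were called lower and 1 transcription factor each way, and with the Col-0 days exchanged 8 transcription factors were called lower. DREB2D fell by 3.44 (SE 0.65) and BZIP10 fell by 1.79 (SE 0.44). ABI3 itself fell by 1.79 (SE 0.49) and FUS3 fell by 3.69 (SE 1.13), while LEC1 and LEC2 had between 0 and 5 counts in total per genotype in all genotypes, too few to compare. Storage members called numbered 5 without Ws at 15 or 17 DAF and 4 without lec1-1 at 15 or 17 DAF. Without lec1-1 at 15, 17 or 21 DAF or Ws at 21 DAF, the LEA genes called lower were 6, 0, 6 and 6, and without lec1-1 at 15 or 17 DAF the oil body genes called were 3 and 1. Transcription factors called lower numbered 2 without lec1-1 at 17 DAF, 3 without Ws at 15 or 17 or lec1-1 at 15 or 21 DAF, and 4 without Ws at 21 DAF.

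Chlorophyll breakdown genes also fell in lec1-1, 5 of 8, the same number adjusted over the list alone, with a median of -2.01 (adjusted p = 0.0266, and adjusted p = 0.352 with an estimated correlation). With library totals 2 of them were higher and 0 lower, and the median was -0.87. PPH, the pheophytinase, fell by 2.49 (SE 0.43). Photosynthesis genes rose: 37 of 42 passed (40 adjusted over the list alone), with a median of 4.63 and an adjusted p of 2.62e-16, and adjusted p = 0.402 with an estimated correlation. The antenna gene LHCA2 rose by 5.75 (SE 1.12), the photosystem genes PSBX and PSAG by 5.08 (SE 1.00) and 4.80 (SE 0.92), and the plastocyanin gene PETE1 by 4.67 (SE 0.84). The level of this list in Ws was low, with a median log2 CPM of 2.46 at 15 DAF against 5.83 in Ler and 5.91 in Col-0. Cell cycle genes rose in 10 of 12 cases (11 adjusted over the list alone), with a median of 4.14, or 3.47 with genes absent from Ws at their bound (adjusted p = 5.23e-06, and adjusted p = 0.283 with an estimated correlation). CYCD3;1, a cyclin of the transition to DNA replication, was at least 31.2-fold higher, the replication helicase gene MCM3 at least 10.3-fold higher and the kinase gene CDKB1;1 at least 9.4-fold higher. The sliding clamp gene PCNA2 rose by 4.09 (SE 0.80). XTH5, a cell wall enzyme gene of the germination list, rose by 5.30 (SE 0.75), the leaf regulator AS1 by 2.84 (SE 0.55) and the actin gene ACT2 by 3.60 (SE 0.48). The largest falls outside the lists were those of the flowering repressor FLC, with a count ratio of 357 (95% interval 63.2 to 14200), the knottin gene AT1G47540 at -6.78 (SE 0.89), AT4G15620 at -6.52 (SE 0.72) and the trypsin inhibitor gene TI2 at -5.82 (SE 0.95). The wax synthesis gene CER1, LOL1 and the chloroplast protein gene CSP41A were at least 33.8-fold, 44.6-fold and 31.5-fold higher.

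In all, edgeR called 3808 of 16085 genes in lec1-1, 2337 higher and 1471 lower, and 3771 of them had the same direction at all 3 days. The count was 1889 without lec1-1 at 17 DAF, 2192 without Ws at 17 DAF, 2432 without Ws at 21 DAF, and 1789, 867 and 2399 without all libraries of 15, 17 or 21 DAF. With library totals it was 6561, and 22 of the 66 named genes called lost the call, among them PPH (-1.35), SEIPIN1 (-0.90) and BZIP10 (-0.67). Of 66 named genes called, 38 kept the call without each single library. Without lec1-1 at 17 DAF 1 of the chlorophyll breakdown genes was called, and 6 of the cell cycle genes were called without it or without Ws at 21 DAF.

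The comparison of abi3-5 with Ler addressed ABI3, which acts in abscisic acid (ABA) responses of the seed. Oil body genes fell in 8 of 8 cases, also adjusted over the list alone, with a median of -3.93 (adjusted p = 4.71e-15, and adjusted p = 0.186 with an estimated correlation). CLO2, a caleosin gene, fell by 4.89 (SE 0.68, n = 3 libraries per genotype, as for all genes of this comparison), CLO1 fell by 4.37 (SE 0.82) and SEIPIN1 fell by 4.24 (SE 0.40). Of 13 storage protein genes 8 fell (9 adjusted over the list alone), with a median of -3.33 (adjusted p = 1.9e-13, and adjusted p = 0.246 with an estimated correlation). SESA3 fell by 7.43 (SE 1.31) and SESA5 fell by 4.62 (SE 0.84). SESA3 is a tandem paralog of SESA1 and SESA4, so its reads may be shared with them. LEA genes fell in 17 of 40 cases and rose in 5 (19 and 5 adjusted over the list alone), with a median of -1.75 (adjusted p = 3.15e-07, and adjusted p = 0.352 with an estimated correlation). EM1 fell by 7.78 (SE 0.90), AT1G72100 fell by 5.74 (SE 0.60) and ECP63 fell by 5.19 (SE 0.50), whereas SAG21 rose by 5.24 (SE 0.62). STS, the stachyose synthase gene, had a count ratio of 331 (95% interval 90.8 to 2740) in Ler over abi3-5, and the peroxiredoxin gene PER1 fell by 5.71 (SE 0.86). Desiccation-induced DSI-1VOC fell by 8.09 (SE 0.66), the superoxide dismutase family gene AT3G56350 fell by 8.25 (SE 0.65), and the neighbouring gibberellin-regulated genes GASA2 and GASA3 stood at -8.43 (SE 0.99) and -7.89 (SE 0.83). ABI3 transcript did not pass, at -1.32 (SE 0.49, adjusted p = 0.106, edgeR). Storage genes called numbered 4 without abi3-5 at 17 DAF and 5 without abi3-5 at 21 DAF. Oil body genes called numbered 3 without Ler at 17 DAF or abi3-5 at 17 or 21 DAF, and LEA genes called lower numbered 9 without Ler at 21 DAF and 8 without abi3-5 at 17 or 21 DAF, with 3 called higher in each. With library totals 13 LEA genes were lower and 9 higher, with a median of -0.38.

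Germination and reserve mobilisation genes rose in abi3-5 in 5 of 14 cases (7 adjusted over the list alone), with a median of 1.43 (adjusted p = 1.08e-05, and adjusted p = 0.283 with an estimated correlation). The expansin gene EXPA2 had a count ratio of 297 (95% interval 53.1 to 11800), the cysteine proteinase gene CP1 rose by 5.82 (SE 1.07) and XTH5 by 3.49 (SE 0.74). Photosynthesis genes rose in 7 of 42 cases (32 adjusted over the list alone), with a median of 2.43 (adjusted p = 1.37e-13, and adjusted p = 0.437 with an estimated correlation). PETE1 rose by 3.91 (SE 0.80), and the rubisco small subunit paralogs RBCS3B and RBCS2B, which may share reads, rose by 3.38 (SE 0.66) and by a count ratio of 22 (95% interval 7.37 to 108). Heat shock protein genes rose in 5 of 17 cases (7 adjusted over the list alone), with a median of 2.57 (adjusted p = 0.00329, and adjusted p = 0.501 with an estimated correlation). HSP18.2 was at least 19.7-fold higher. Its call ended without Ler at 15 DAF (log2 fold change 6.68), and that of the whole list fell to 0 members without that library, 1 without Ler at 17 DAF or abi3-5 at 15 DAF, and 3 without abi3-5 at 21 DAF, and the list median was 0.42 without abi3-5 at 15 DAF. Fes1B and XTH19 were at least 31.7-fold and 19.2-fold higher, and ACT2 rose by 2.17 (SE 0.45). Chlorophyll breakdown genes fell in 3 of 8 cases, also adjusted over the list alone, with a median of -0.71 that was 0.73 with library totals (adjusted p = 0.0248, and adjusted p = 0.32 with an estimated correlation). With library totals 2 members were called higher and 0 lower. None of the 3 was called without abi3-5 at 17 or 21 DAF. Germination genes called numbered 3 without Ler at 15 or 17 DAF or abi3-5 at 21 DAF. Photosynthesis genes called numbered 4 without Ler at 15 or abi3-5 at 17 DAF, and 3 without Ler at 17 or 21 or abi3-5 at 21 DAF. With library totals 38 photosynthesis, 13 germination and 11 heat shock protein genes were called higher. Photosynthesis genes called numbered 11 with upper quartile scaling, 18 with the Col-0 days exchanged and 15 without those Col-0 libraries.

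In all, 1285 genes changed in abi3-5, 682 higher and 603 lower, and 1257 of them had the same direction at all 3 days. The count was 786, 688 and 705 without Ler at 15, 17 or 21 DAF, 704 and 451 without abi3-5 at 17 or 21 DAF, and 825, 285 and 425 without all libraries of 15, 17 or 21 DAF. It was 1952 with DESeq2, 716 without the day in the model, 822 with each ecotype fitted alone, 1939 with the Col-0 days exchanged and 8029 with library totals. Of 50 named genes called, 26 kept the call without each single library.

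The comparison of fus3-3 with Col-0 addressed FUS3, a further regulator of maturation. All of the 13 storage protein genes fell adjusted over the list alone, 9 of them over all genes tested, with a median of -3.05 (adjusted p = 8.53e-08, and adjusted p = 0.283 with an estimated correlation). CRB fell by 5.63 (SE 1.12, n = 3 libraries per genotype, as for all genes of this comparison). Of 8 oil body genes 5 fell (6 adjusted over the list alone, median -2.31, adjusted p = 2.51e-05, and adjusted p = 0.32 with an estimated correlation), among them CLO2 at -2.81 (SE 0.61) and SEIPIN1 at -2.09 (SE 0.35). Oil and fatty acid synthesis genes fell in 6 of 21 cases (7 adjusted over the list alone), with a median of -1.08 that was 0.22 with library totals (adjusted p = 0.0177, and adjusted p = 0.652 with an estimated correlation). The sucrose synthase gene SUS2 fell by 8.23 (SE 1.58). Of 9 raffinose and inositol genes 3 fell and 1 rose (median -1.41), and with library totals 2 were lower and 2 higher (median -0.70). The list median was 0.24 without the Col-0 libraries labelled 17 and 21 DAF, which leaves 1 Col-0 library. MIPS1 and MIPS2, which make inositol phosphate, fell by 5.36 (SE 1.11) and fell by 2.58 (SE 0.48). Among antioxidant genes, 4 of 15 fell (5 fell and 1 rose adjusted over the list alone, median -1.08, adjusted p = 0.026, and adjusted p = 0.32 with an estimated correlation), led by the superoxide dismutase genes CSD2 at -5.85 (SE 0.59) and CSD1 at -3.37 (SE 0.48). With library totals 3 antioxidant genes were higher and 2 lower, with a median of -0.09. Of the ABA list 8 of 24 genes fell and 3 rose (12 and 4 adjusted over the list alone), with a median of -1.06 (adjusted p = 0.0548 by camera, which did not pass). With library totals 5 were higher and 2 lower, and the median was 0.01. The dormancy gene DOG1 fell by 3.84 (SE 0.75), NCED9 of ABA synthesis fell by 3.65 (SE 0.83) and the kinase gene SNRK2.6 rose by 2.62 (SE 0.66). Of the seed transcription factors 5 of 17 fell and 1 rose (6 and 1 adjusted over the list alone, median -1.31, adjusted p = 0.0153, and adjusted p = 0.32 with an estimated correlation). DREB2D fell by 3.17 (SE 0.64) and ABI4 rose by 2.14 (SE 0.52). With library totals 3 transcription factors were higher and 3 lower (median -0.17), 3 oil body genes were lower, and 1 oil synthesis gene was higher and 3 lower. ABI3 fell by 1.60 (SE 0.49), and FUS3 itself did not pass at -1.75 (SE 1.02, adjusted p = 0.237, edgeR). Storage genes called numbered 2 without Col-0 at 21 DAF and 4 without fus3-3 at 17 DAF, oil body genes 3 without Col-0 at 21 or fus3-3 at 15 DAF and 2 without fus3-3 at 17 DAF. Oil synthesis genes called numbered 1, 3 and 2 without these libraries in turn, the transcription factors called lower 3, 2 and 1, and the antioxidant genes 2 without Col-0 at 21 or fus3-3 at 17 DAF, with a list median of 0.08 without Col-0 at 17 DAF. ABA genes called lower numbered 4 without Col-0 at 21 or fus3-3 at 21 DAF and 3 without fus3-3 at 17 DAF.

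Cell cycle genes rose in fus3-3 in 5 of 12 cases (9 adjusted over the list alone), with a median of 3.11, or 2.92 with absent genes at their bound (adjusted p = 0.000184, and adjusted p = 0.352 with an estimated correlation). CYCD3;1 had a count ratio of 51.8 (95% interval 9.2 to 2060). Photosynthesis genes rose in 7 of 42 cases (5 adjusted over the list alone), with a median of 1.71 (adjusted p = 0.000184, and adjusted p = 0.708 with an estimated correlation). Chlorophyll breakdown genes fell in 5 of 8 cases, also adjusted over the list alone (median -1.90, adjusted p = 0.00983, and adjusted p = 0.283 with an estimated correlation), among them NYE2, a stay-green gene of chlorophyll removal, at -3.28 (SE 0.73). Germination genes rose in 5 of 14 cases (6 adjusted over the list alone, median 1.29, adjusted p = 0.00889, and adjusted p = 0.437 with an estimated correlation), with XTH5 at 5.05 (SE 0.68) and EXPA2 at 2.98 (SE 0.67). Of 40 LEA genes 9 fell and 5 rose (10 and 6 adjusted over the list alone), and the list was not called by camera (median -0.90, or 0.09 without Col-0 at 17 DAF, adjusted p = 0.449). With library totals 8 were higher and 5 lower (median -0.14), and without the Col-0 libraries labelled 17 and 21 DAF, with 1 Col-0 library left, 2 were higher and 0 lower (median -0.09). SAG21 rose by 5.57 (SE 0.63) and DI21 by 5.01 (SE 0.70). ACT2 rose by 3.74 (SE 0.48) and AS1 by 2.35 (SE 0.55). The trypsin inhibitor gene TI2 fell by 8.13 (SE 1.12), the terpenoid cyclase gene AT1G78500 fell by 9.71 (SE 1.77), and the oxygenase gene AT1G77330 was at least 32-fold higher. Cell cycle genes called numbered 1 without Col-0 at 15 DAF and 2 without Col-0 at 21 or fus3-3 at 17 DAF, and germination genes 3 without Col-0 at 15 or 21 DAF. Photosynthesis genes called numbered 1 without Col-0 at 17 or 21 DAF, 16, 0 and 2 without fus3-3 at 15, 17 or 21 DAF, and 1 chlorophyll breakdown gene was called without fus3-3 at 17 DAF. With library totals 1 chlorophyll breakdown gene was higher and 1 lower (median -0.93), and 30 photosynthesis, 11 cell cycle and 8 germination genes were higher. With the Col-0 days exchanged 12 photosynthesis genes were called. LEA genes called lower numbered 1 without Col-0 at 17 or fus3-3 at 17 DAF and 3 without fus3-3 at 15 DAF.

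In all, 3057 genes changed in fus3-3, 1663 higher and 1394 lower, and 2721 of them had the same direction at all 3 days. The Col-0 libraries labelled 17 and 21 DAF weigh on this count, which was 460 without both and 1581 without the second alone. Without both, Col-0 is a single library of 15 DAF, whose spread is taken from the other genotypes, so the calls lost there do not show that the changes were absent. Without fus3-3 at 17 DAF it was 1159, without all libraries of 15, 17 or 21 DAF 1562, 1028 and 1678, with Ws and Ler left out of the fit 114, with a day effect per ecotype 1963, without the day in the model 1863 and with library totals 5903. Of 71 named genes called, 33 kept the call without each single library, 47 lost it without the Col-0 libraries labelled 17 and 21 DAF, and 49 lost it with each ecotype fitted alone. Of the genes named here CSD2, SUS2, SAG21, ACT2, XTH5, TI2, AT1G78500 and AT1G77330 were called in all of these. Without the pair of Col-0 libraries 4 storage and 0 oil body genes were called, with list medians of -3.44 and -2.10. In that setting 0 chlorophyll breakdown (-1.17) and 0 photosynthesis genes (0.98) were called, 1 germination (2.1) and 2 cell cycle genes (5.92) higher, and 2 transcription factors (-0.87), 3 oil synthesis (-0.92), 1 ABA (-0.50) and 2 antioxidant genes (0.08) lower, with list medians in parentheses.

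**Figure D1:**
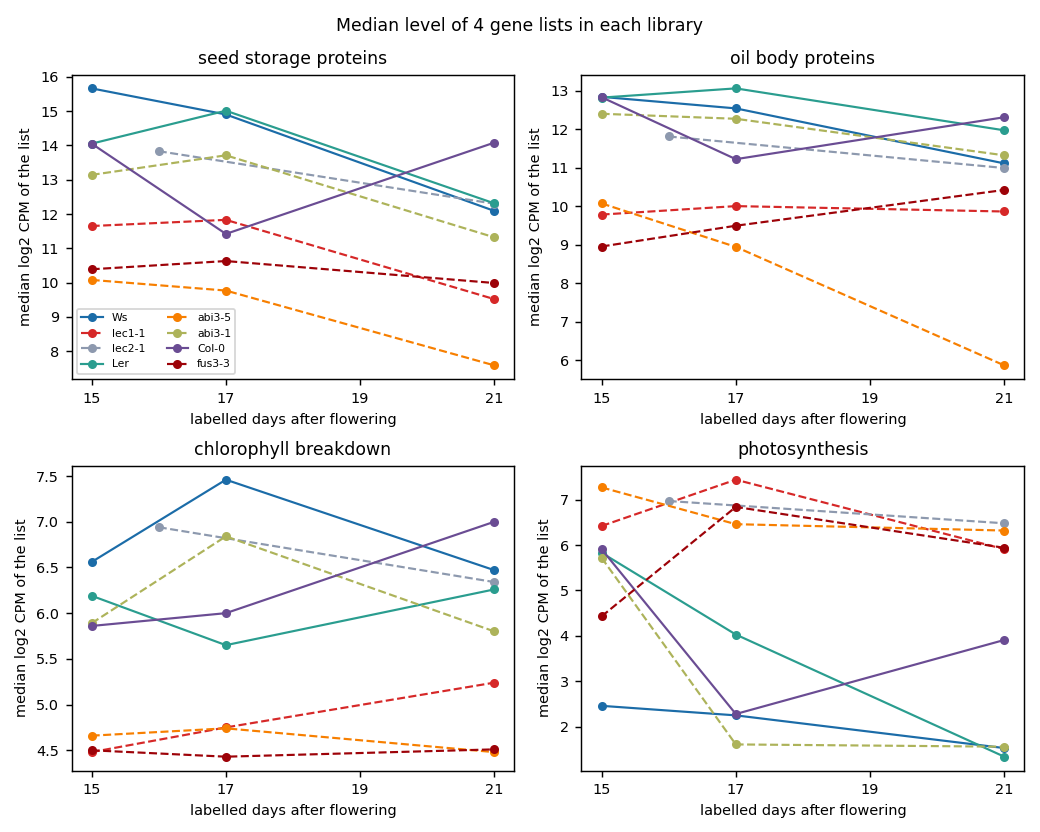
Median level (log2 CPM) of 4 gene lists in each library against the labelled days after flowering, with wild types as solid and mutants as dashed lines, 1 point per library, and the single lec2-1 library of 15 and 17 DAF drawn midway. At 15 DAF storage genes stood at 15.66 in Ws and 11.65 in lec1-1, and photosynthesis genes at 2.46 in Ws and 6.42 in lec1-1.

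The comparison of lec2-1 with Ws asked what a tolerant mutant shares with this background. Photosynthesis genes rose: 34 of 42 passed (40 adjusted over the list alone), with a median of 5.01 (adjusted p = 2.16e-57, and adjusted p = 0.246 with an estimated correlation). PETE1 rose by 5.90 (SE 0.88, n = 2 libraries of lec2-1 and 3 of Ws, as for all genes of this comparison). The level of the list was low in Ws, as given above for lec1-1, and plastid transcripts took 0.206% or more of the counts of lec2-1. Without Ws at 15, 17 or 21 DAF 2, 1 and 2 of these genes were called, and without lec2-1 at 15 and 17 DAF or at 21 DAF 3 and 2, with medians between 4.42 and 5.37. Seed coat flavonoid genes rose in 2 of 10 cases (5 adjusted over the list alone), with a median of 3.28, or 2.33 with genes absent from Ws at their bound (adjusted p = 6.82e-06, and adjusted p = 0.283 with an estimated correlation), and 0 were called without any 1 of the 5 libraries and 5 with library totals. No storage protein gene passed, with 0 of 13 also adjusted over the list alone, and the list median was -1.06 (adjusted p = 0.00258, and adjusted p = 0.487 with an estimated correlation). For oil body genes 0 of 8 passed in both ways of adjusting and the median was -0.88 (adjusted p = 0.0168, and adjusted p = 0.522 with an estimated correlation). Of 40 LEA genes 1 was called lower and 1 higher, and with library totals 1 lower and 4 higher. The LEA gene AT3G17520 fell by 8.02 (SE 0.94), and the bromodomain gene AT3G27420 was at least 48.1-fold lower. The transcription factor gene MYB47 was at least 34.5-fold higher, AT3G28270 at least 210-fold higher, and AT3G28220 had a count ratio of 1010 (95% interval 180 to 39800). WNK8 (AT5G41990) and the overlapping AT5G41992 had identical values of -3.05 (SE 0.59), so that the reads cannot be assigned to either. Their call ended without Ws at 17 DAF (-2.96) and without lec2-1 at 15 and 17 DAF (-3.45) or 21 DAF (-2.63).

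In all, edgeR called 303 genes in lec2-1, 297 higher and 6 lower, each the same way in both ratios. The count was 59, 55 and 79 without Ws at 15, 17 or 21 DAF, 57 and 75 without lec2-1 at 15 and 17 or at 21 DAF, and 78, 30 and 77 without all libraries of 15, 17 or 21 DAF. It was 105 without the day in the model, 565 with each ecotype fitted alone, 458 with both identical columns kept and 757 with library totals. Of 19 named genes called, 6 kept the call without each single library. Of the 297 higher genes, 127 were also higher in abi3-5 (12.6 expected of independent lists) and 180 in fus3-3 (30.7 expected). Those comparisons use other libraries but the same fit, so the lists are not independent. The median of the 297 genes in abi3-1 was -0.16.

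The comparison of abi3-1 with Ler asked the same of the weaker abi3 allele. Only BPS2 changed by edgeR, 1 of 16085 genes, with 269 at an unadjusted p under 0.05 and 2 called by DESeq2. It fell by 2.59 (SE 0.38, adjusted p = 0.0216, edgeR), from 57.5 CPM (SD 23.2, n = 3) in Ler to 9.31 (SD 0.73, n = 3), the same way at all 3 days. The count was 0 without Ler at 17 or 21 DAF, without abi3-1 at 15, 17 or 21 DAF, without all libraries of any 1 day, with library totals, with a day effect per ecotype or with each ecotype fitted alone, and BPS2 then stood between -2.81 and -2.25. No member of the storage, oil body, LEA, photosynthesis or cell cycle lists passed, and their medians were -0.52, -0.61, 0.11, -0.50 and -0.54. The LEA median was -0.16 without Ler at 17 DAF, -0.14 and -0.09 without abi3-1 at 17 or 21 DAF, and 0.60 and 0.44 without Ler at 21 or abi3-1 at 15 DAF. The photosynthesis median was 0.43 without Ler at 15 DAF, 0.03 without abi3-1 at 17 DAF and -2.78 without abi3-1 at 15 DAF. By camera the storage list (adjusted p = 0.0266, and adjusted p = 0.594 with an estimated correlation) and the photosynthesis list (adjusted p = 5.23e-06, and adjusted p = 0.61 with an estimated correlation) were called lower. In simulated data of this comparison 32.8% of genes changed 4-fold and 81.8% of those changed 8-fold were recovered, and 83 genes were called in all.

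The aim of the series was to find genes that set the intolerant mutants apart from the tolerant ones. In the contrast of lec1-1 with lec2-1 and abi3-5 with abi3-1, storage protein genes were lower in 10 of 13 cases (11 adjusted over the list alone), with a median of -2.54 (adjusted p = 1.43e-11, and adjusted p = 0.261 with an estimated correlation). SESA3 stood at -4.55 (SE 0.82, n = 6 intolerant and 5 tolerant libraries, as for all genes of this comparison), CRB at -4.06 (SE 0.75) and SESA5 at -3.30 (SE 0.58). These libraries are days of the same 4 genotypes, lec1-1 and abi3-5 against lec2-1 and abi3-1. The SE holds no spread between genotypes of a class, so the p values do not extend to other intolerant or tolerant mutants. Oil body genes were lower in 6 of 8 cases (8 adjusted over the list alone), with a median of -2.73 (adjusted p = 8.66e-10, and adjusted p = 0.261 with an estimated correlation), among them CLO1 at -3.05 (SE 0.56), CLO2 at -3.04 (SE 0.45) and SEIPIN1 at -2.76 (SE 0.27). LEA genes were lower in 19 of 40 cases and higher in 7 (21 and 8 adjusted over the list alone), with a median of -1.68 (adjusted p = 2.81e-05, and adjusted p = 0.449 with an estimated correlation). ATECP31 stood at -5.27 (SE 0.97), AT3G15670 at -4.19 (SE 0.55), ECP63 at -3.03 (SE 0.33) and SAG21 at 3.90 (SE 0.46). Raffinose family and inositol genes were lower in 3 of 9 cases (4 adjusted over the list alone, median -1.47, adjusted p = 0.0143, and adjusted p = 0.276 with an estimated correlation): STS stood at -4.55 (SE 0.65), GOLS2 at -3.47 (SE 0.67) and MIPS2 at -2.18 (SE 0.34). Chlorophyll breakdown genes were lower in 4 of 8 cases (5 adjusted over the list alone, median -1.39, adjusted p = 0.00746, and adjusted p = 0.283 with an estimated correlation), with NYE2 at -2.58 (SE 0.51) and NYE1 at -2.21 (SE 0.40). Seed transcription factors were lower in 5 of 17 cases and higher in 1, the same numbers adjusted over the list alone (median -0.90, adjusted p = 0.012, and adjusted p = 0.32 with an estimated correlation). The heat stress factor HSFA9 stood at -5.49 (SE 1.12), DREB2D at -2.27 (SE 0.46) and ABI4 at 2.25 (SE 0.44). Without lec2-1 at 15 and 17 DAF 12 LEA genes were called lower and 4 higher, 3 oil body genes were called, and 3 transcription factors were called lower, as were 2 without lec2-1 at 21 DAF. With library totals 13 LEA genes were lower and 8 higher (median -0.79), 2 transcription factors were lower and 1 higher (median -0.11), and 2 chlorophyll breakdown genes were lower and 1 higher (median -0.53). For lec1-1 against lec2-1 alone 0 storage, 0 oil body and 0 transcription factor genes were called, with medians of -1.85, -1.33 and -1. There 1 LEA gene was called, higher (median -0.78), 1 gene of the raffinose list and 1 of chlorophyll breakdown, and ECP63 stood at -0.66 (adjusted p = 0.473, edgeR).

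Cell cycle genes were higher in the intolerant than in the tolerant mutants in 11 of 12 cases, also adjusted over the list alone, with a median of 3.03, or 2.75 with absent genes at their bound (adjusted p = 8.53e-08, and adjusted p = 0.283 with an estimated correlation). PCNA1 was at least 15.3-fold higher, MCM2 had a count ratio of 25 (95% interval 6.74 to 209) and MCM7 stood at 3.90 (SE 0.71). Germination genes were higher in 6 of 14 cases (7 adjusted over the list alone, median 0.98, adjusted p = 0.00162, and adjusted p = 0.365 with an estimated correlation), with XTH5 at 4.21 (SE 0.55) and EXPA2 at 4.13 (SE 0.65). The gibberellin synthesis gene GA3OX2 had a count ratio of 37.7 (95% interval 6.57 to 1510). Shoot apex and leaf regulators were higher in 2 of 6 cases (4 adjusted over the list alone, median 1.71, adjusted p = 0.0298, and adjusted p = 0.283 with an estimated correlation). Photosynthesis genes were higher in 6 of 42 cases, also adjusted over the list alone, with a median of 1.4 that was -0.25 for lec1-1 against lec2-1 alone (adjusted p = 1.2e-06, and adjusted p = 0.597 with an estimated correlation). IGMT5, a methyltransferase gene, stood at 6.41 (SE 0.64), the glucosidase gene BGLU21 at 6.41 (SE 0.90) and AT3G20370 at 6.65 (SE 0.93). On the lower side the histone gene AT1G08170 stood at -5.99 (SE 0.77), AT3G25160 at -5.38 (SE 0.71) and the papain family gene AT4G11310 at -4.94 (SE 0.73). Cell cycle genes called numbered 7 without lec1-1 at 17, abi3-5 at 21 or abi3-1 at 17 DAF, 6 without lec2-1 at 15 and 17 DAF and 5 without lec2-1 at 21 DAF. Without lec2-1 at 21 DAF 3 germination genes were called. Photosynthesis genes called numbered 2 without lec1-1 at 17 or abi3-5 at 21 DAF, 1 without lec2-1 at either time or abi3-1 at 17 DAF, 24 without abi3-1 at 15 DAF and 3 without abi3-1 at 21 DAF. With library totals 31 photosynthesis and 5 shoot apex genes were higher, and with the Col-0 days exchanged 9 photosynthesis genes. For lec1-1 against lec2-1 alone 1 cell cycle, 1 germination, 0 shoot apex and 0 photosynthesis genes were called, with medians of 3.36, 0.14, 1.33 and -0.25.

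In all, 2726 genes passed in this contrast, 1523 higher and 1203 lower, and 2275 of them had the same direction in all 5 ratios. The count was 1677 without lec1-1 at 17 DAF, 847 and 1438 without lec2-1 at 15 and 17 or at 21 DAF, 1661 without abi3-5 at 21 DAF, 1764 without abi3-1 at 17 DAF, 937 and 956 without all libraries of 17 or 21 DAF, and 5461 with library totals. For lec1-1 against lec2-1 alone it was 204, and 54 of the 65 named genes called lost the call there, while MIPS2, XTH5, IGMT5, BGLU21, AT3G20370 and AT1G08170 were among those that kept it. Of the 65, 46 kept the call without each single library.

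**Figure D2:**
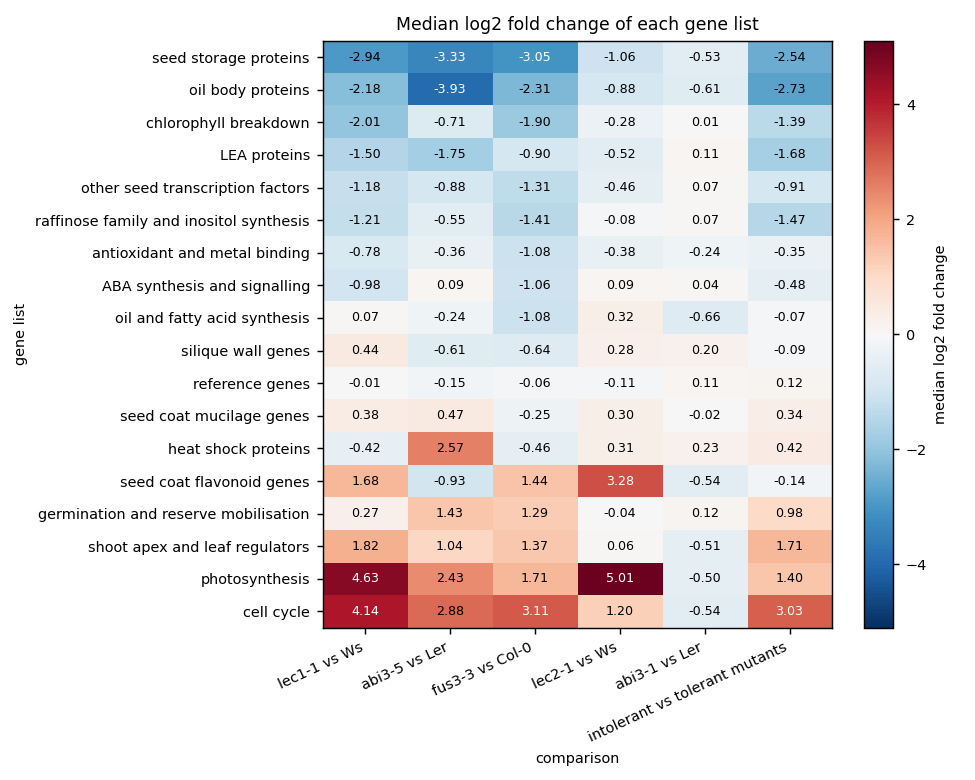
Median log2 fold change of 18 gene lists (vertical axis) in 6 comparisons (horizontal axis), each value printed in its cell, red for higher and blue for lower in the mutant or in the intolerant mutants. Storage genes stood at -2.94, -3.33 and -3.05 in lec1-1, abi3-5 and fus3-3 and at -1.06 and -0.52 in lec2-1 and abi3-1. With library totals medians below 0 turned above it in several lists. Among them were transcription factors in lec1-1 (0.01) and abi3-5 (0.53), chlorophyll breakdown in abi3-5 (0.73), and oil synthesis in abi3-5 (1.34) and fus3-3 (0.22). Others were heat shock proteins in lec1-1 (0.69) and fus3-3 (0.61), ABA genes in lec1-1 (0.32) and LEA genes in lec2-1 (0.15). The median of all genes was then 1.21 in lec1-1, 1.49 in abi3-5, 1.14 in fus3-3 and 0.66 in lec2-1. Each list median named for that scaling lay below that of all genes in its mutant.

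The core of genes called the same way in lec1-1, abi3-5 and fus3-3 against their own wild types and in the contrast with the tolerant mutants held 261 lower and 380 higher genes. With library totals its lower side was far smaller and its higher side far larger. With each ecotype fitted alone both sides were far smaller, and these counts are given with the other settings below. The 3 intolerant mutants and their wild types use separate libraries, and 268 genes were lower in all 3 where 4.78 were expected of independent lists, and 406 were higher where 10.2 were expected. The comparisons share 1 fit, with its spread per gene and its day effects. The lists are therefore not independent, and these expected numbers set no level of chance. Across genes the fold changes of lec1-1 correlated with those of abi3-5 at r = 0.62 and of fus3-3 at 0.773, and those of abi3-5 and fus3-3 at 0.644 (genes are not independent replicates). The core was chosen by these comparisons and by the contrast with the tolerant mutants. Its medians, given here for each mutant, therefore follow in part from that choice. The lower core genes had median log2 fold changes of -2.32, -2.46 and -2.30 in lec1-1, abi3-5 and fus3-3, against -0.60 in lec2-1 and -0.15 in abi3-1. Among them were 5 of 8 oil body genes (OLEO1, OLEO4, CLO1, CLO2 and SEIPIN1, 0.13 expected) and 5 of 13 storage genes (CRB, CRD, SESA3, SESA4 and SESA5, 0.211 expected), with adjusted p values of 2.1e-06 and 2.25e-05 in Fisher's exact test, 1-sided. This test treats the members of a list as independent, though tandem paralogs such as SESA3 and SESA4 may share reads, and of 56 list calls by camera in 142 tests 0 were kept with an estimated correlation. The core also held 3 of 8 chlorophyll breakdown genes (NYE1, NYE2 and PPH, adjusted p = 0.00267, exact), 3 of 17 transcription factors (HSFA9, DREB2D and AGL67, adjusted p = 0.0218, exact) and 4 of 40 LEA genes (AT1G72100, AT3G15670, ATECP31 and AT5G53270, adjusted p = 0.0282, exact). STS and MIPS2 of the raffinose and inositol list were in it too (adjusted p = 0.0525, exact, which did not pass). With library totals 0 chlorophyll breakdown genes were called lower in lec1-1 or abi3-5, and 1 transcription factor in each. In lec1-1 that scaling left 3 LEA, 2 oil body and 0 raffinose and inositol genes called lower. NYE1 lost its call in lec1-1 without lec1-1 at 17 DAF (-1.84), in abi3-5 without abi3-5 at 17 (-2.36) or 21 DAF (-2.15), and in fus3-3 without Col-0 at 17 (-0.88) or fus3-3 at 17 DAF (-1.65). HSFA9, at -4.35 in fus3-3, turned to 3.15 there without the Col-0 libraries labelled 17 and 21 DAF (adjusted p = 0.796, edgeR), and PPH, at -1.37 in abi3-5, stood at 0.06 with library totals. The higher core genes had medians of 3.53, 2.82 and 2.89 in the intolerant mutants, 1.80 in lec2-1 and -0.08 in abi3-1. They included the LEA genes SAG21, DI21, AT1G54410 and AT2G44060 (4 of 40, adjusted p = 0.0737, exact, which did not pass), RBCS2B, RBCS3B and PSBQ1 of photosynthesis, XTH5, MCM7 and ACT2. The photosynthesis list did not pass either (3 of 42, 0.992 expected, adjusted p = 0.344, exact). Nor did the germination (adjusted p = 0.931, exact), cell cycle (adjusted p = 0.898, exact) and reference lists (adjusted p = 0.775, exact), with 1 member each. Of the 380 higher core genes 90 (23.7%) were also called higher in the tolerant mutant lec2-1, where 7.02 were expected of independent lists. Of the 261 lower ones 0 were called lower. Only 6 genes were called lower in lec2-1, and 0.0974 were expected to be shared, so this 0 carries no information. In 20 simulations of unchanged lec2-1 libraries against the same Ws libraries a median of 0 genes was called in lec2-1 and 0 were shared, so that with few or no calls to share they set no level of chance for the 90. The core and lec2-1 share the Ws libraries, which are too few to split, so part of the excess may come from them. RBCS3B, PSBQ1 and SAG21 were among the 90, at 3.68 (SE 0.69), 3.95 (SE 0.92) and 3.45 (SE 0.60). RBCS3B had 61.6 and 24.7 normalized CPM in the lec2-1 libraries and 21.2, 58.4 and 24.9 in lec1-1, and it stood at -0.44 for lec1-1 against lec2-1 alone. Its call in the contrast ended without lec1-1 at 17 (1.36) or 21 DAF (1.38), lec2-1 at 15 and 17 (1.57) or 21 DAF (1.31), abi3-5 at 21 DAF (1.05), or abi3-1 at 17 (1.34) or 21 DAF (1.3).

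The lower core held 173 genes without Ws at 15 DAF, 131 without lec1-1 at 17 DAF, 172 without lec2-1 at 15 and 17 DAF, 142 and 132 without abi3-5 at 17 or 21 DAF and 122 without fus3-3 at 17 DAF. The higher core held 210 and 227 genes without lec2-1 at 15 and 17 or at 21 DAF, 230, 220 and 183 without Ler at 15, 17 or 21 DAF, 137 without abi3-5 at 21 DAF and 224 without fus3-3 at 17 DAF. Without all libraries of 15, 17 or 21 DAF the lower core held 118, 20 and 93 genes and the higher core 184, 64 and 81. Without the Col-0 libraries labelled 17 and 21 DAF, with 1 Col-0 library left, they held 90 and 111, and with lec1-1 against lec2-1 alone in the last step 44 and 42.

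**Figure D3:**
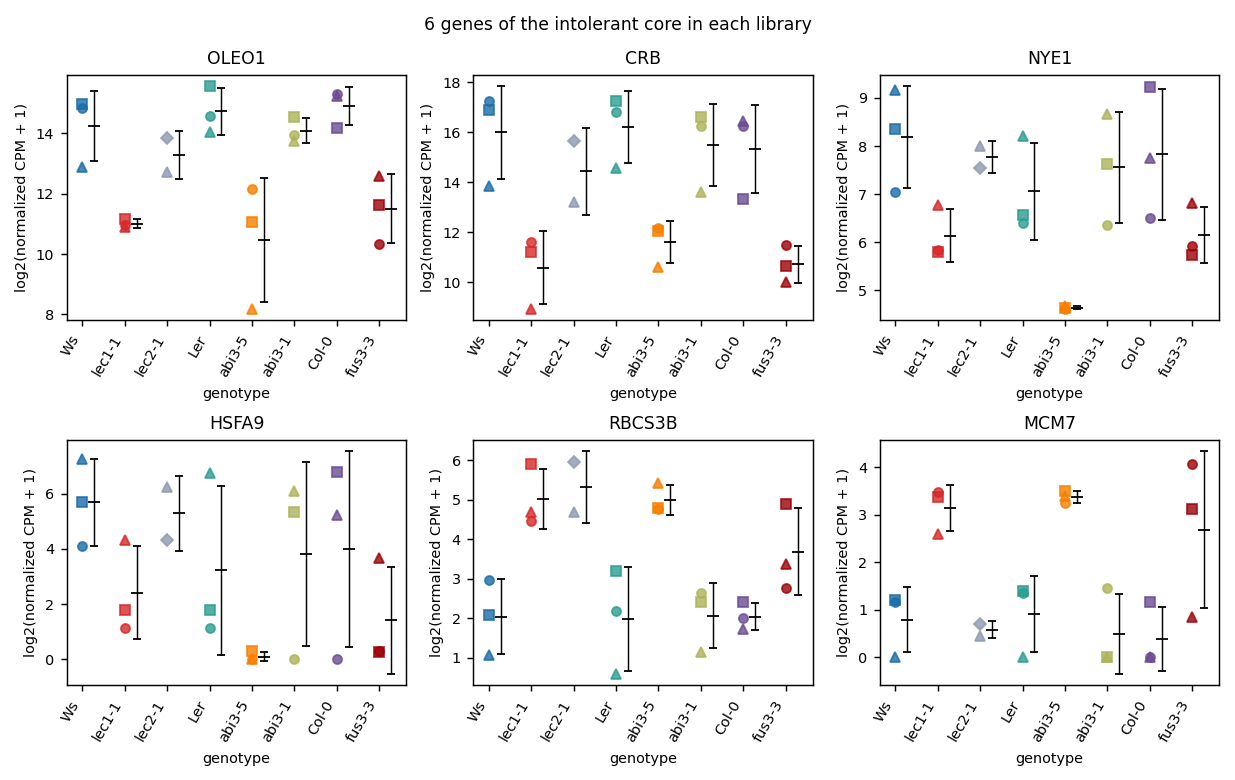
Level of 6 core genes, log2 of normalized CPM plus 1, in each library by genotype, with circles for 15, squares for 17 and triangles for 21 DAF, diamonds for the lec2-1 library of 15 and 17 DAF, and bars for the mean and SD over libraries. CRB ran from 14900 to 155000 normalized CPM in Ws and from 487 to 3160 in lec1-1, and MCM7 from 0 to 1.3 in Ws and from 5.04 to 10.2 in lec1-1.

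The last comparison asked whether the change over the days differs between intolerant mutants and wild types. It called 0 of 16085 genes by edgeR, with 1081 at an unadjusted p under 0.05 and 12 called by DESeq2. The count was 17 without the Col-0 library labelled 21 DAF, 1 without lec1-1 at 21 DAF, 27 without the Col-0 libraries labelled 17 and 21 DAF (1 Col-0 library left), and 458 with their days exchanged. Photosynthesis genes had a median slope difference of 0.31 log2 per day with 0 of 42 genes called in both ways of adjusting (adjusted p = 1.13e-11 by camera, and adjusted p = 0.487 with an estimated correlation). In simulated data 45.5% of genes whose change differed 8-fold were recovered, and 2.99% of those that differed 4-fold.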

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

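All tests of this part were chosen after the results were seen, except that of library depth. Differences between the effects of mutants were tested as contrasts in edgeR and, for lists, by camera. None of the list differences was called with an estimated correlation.

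The effects of abi3-5 and lec1-1, each against its own wild type, differed in 54 genes, 11 of them higher in abi3-5, those of abi3-5 and fus3-3 in 45, and those of lec1-1 and fus3-3 in 1. Of the 54, 6 were called in opposite directions in the 2 mutants: the RING/U-box gene AT1G67856 fell by 5.54 in abi3-5 and rose by 5.52 in lec1-1 (difference -11.07, SE 1.41), and the methionine sulfoxide reductase gene MSRB5 fell by 3.22 and rose by 3.08. Against lec1-1 the effect of abi3-5 was lower, as a median difference in log2, for LEA proteins (-0.886), oil body proteins (-1.91), photosynthesis (-2.1) and flavonoid genes (-3.16), and higher for heat shock proteins (2.37), ABA genes (0.783) and germination (1.21). Against fus3-3 it was lower for LEA proteins (-1.17), oil body proteins (-2) and flavonoid genes (-2.24), and higher for oil synthesis (0.599), heat shock proteins (2.66), ABA genes (0.941) and photosynthesis (0.6). Against fus3-3 the effect of lec1-1 was lower for LEA proteins (-0.297) and higher for oil synthesis (1.3) and photosynthesis (2.89). Of the tolerant mutants, the effect of lec2-1 was lower than that of abi3-1 for LEA proteins (-0.641) and higher for photosynthesis (5.5) and flavonoid genes (3.4). Of 40 LEA genes 3 were called singly for abi3-5 against lec1-1 and 3 for abi3-5 against fus3-3. For lec1-1 against fus3-3 it was 0, and for lec2-1 against abi3-1 it was 1. No member of the other lists named in this paragraph was called. The rise of heat shock protein genes in abi3-5 depended on single libraries, as given above. The mutants of each pair are in different ecotypes, which cannot be separated from the mutation here.

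A maturation score, 0 at 15 and 1 at 21 DAF from 821 genes of Ws and Ler, moved from 17 to 21 DAF by 0.69 in Ws and 0.94 in Ler and by -0.75 in Col-0, a difference that was not tested. Its genes were chosen to differ at least 4-fold between 15 and 21 DAF in Ws and Ler, so a score near 1 at 21 DAF is built in there. A pace of maturation faster or slower than in the other wild types would leave the score rising with the labelled day, and the value of -0.75 argues against it. That value also prompted the question and rests on 1 Col-0 library per day, so it is not a separate test. At equal depth the change was -0.73, which argues against library depth. If the days of these 2 Col-0 libraries had been exchanged, the one labelled 21 DAF would score near 17 DAF of the others, and its 0.22 lies between 0.02 in Ler and 0.36 in Ws. That score was part of what prompted the question, so it cannot test an exchange, which stays open. A single wrong label and other differences between the plants were not tested.

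Photosynthesis genes were higher in lec2-1 than in Ws. With library totals, which leave out the composition factors, the median was 5.77. These factors were lower in Ws (0.527, 0.566 and 1.06) than in lec2-1 on the same days (0.962 and 1.38). Leaving them out could therefore only raise the median, so this setting is no test of scaling. There the list lay 5.11 above the median of all genes. A factor shared by all genes of a library does not change such an excess. A delay of maturation within 15 to 21 DAF would raise oil synthesis genes as well. Their median was 0.31 with TMM and 1.04 with library totals, where that of all genes was 0.66. The maturation score of lec2-1 was 0.76 at 21 DAF against 1.05 in Ws. In its other library it was 0.38, against 0.09 and 0.36 in Ws at 15 and 17 DAF. A delay therefore stays open. The photosynthesis level in Ws at 15 DAF lay 3.37 log2 units below the nearer of Ler and Col-0 (-3.37), so a low level in the Ws libraries may account for part of the difference. Whether green maternal tissue contributed cannot be told apart with 3 silique wall genes tested (median 0.28).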

How the results depend on the processing

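The settings that move or leave out Col-0 libraries, use Ws and Ler alone or keep both lec2-1 columns, and the splits of single comparisons and of the intolerant and tolerant mutants, were chosen after the results were seen. Of 618 values of named genes, 272 of them called, 14367 of 16057 values in other settings had the same direction and side of the threshold, 1025 were no longer called, 512 became called and 153 reversed. Of the reversed values 3 were called: PPH in abi3-5 with library totals (0.06), HSFA9 in fus3-3 without the Col-0 libraries labelled 17 and 21 DAF (3.15) and RBCS3B between intolerant and tolerant mutants with lec1-1 against lec2-1 only (-0.44). With RLE, upper quartile, limma-trend and the robust fit each count of genes stayed within 1.5 times its value. The cause of the changes below was not tested unless named.

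Values not called in either setting turned with library totals in lec1-1 (DGAT3 0.40), lec2-1 (GOLS2 0.27, AGL67 0.36, CSD2 0.01, PMEI6 0.14, STS 0.34, BZIP10 0.11, AGL15 0.00, PPH 0.08, DIN10 0.33), abi3-5 (ETC1 0.23, DGAT1 0.76, CSD2 0.07, TT5 0.09, SUS3 0.25, NYC1 0.40, RPL 0.87, YLS8 0.41), abi3-1 (ACT8 0.12, GL2 0.07, RPL 0.07), fus3-3 (GATL5 0.60, RPL 0.63, YLS8 0.05), intolerant against tolerant mutants (SAND 0.19, RPL 0.72) and wild types (SAND 0.02). In lec2-1 they did so with its library at 15 DAF only (GOLS2 0.49, HSFA9 0.19), with both columns (GOLS2 0.06) and without the day in the model (FIL -0.26), the last also in abi3-1 (HSFA9 -0.06). Limma-trend turned APX1 0.04 in abi3-1, LDOX -0.16 between intolerant and tolerant mutants and PCNA1 -0.08, SHP2 0.18, CDKB1;1 -0.09, MCM7 -0.07 for the slope. Between intolerant and tolerant mutants SHP2 0.67, LDOX -1.46, RPL 0.16, HSP17.6II -0.01 turned with lec1-1 against lec2-1 only, and RPL with RLE (0.03), DESeq2 (0.03) and a day effect per ecotype (0.01). For the slope CRD 0.11, CDKB1;1 -0.01 turned with the Col-0 days exchanged and CRD 0.10 without these libraries.

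Leaving out 1 library or 1 day turned further uncalled values, given as ranges. In lec1-1 this was RPL -0.10 to 0.84, in abi3-5 ETC1 -1.82 to 0.09, RPL -1.53 to 0.24, TT5 -2.09 to 0.06, in fus3-3 KNAT1 -0.03 to 1.7, between intolerant and tolerant mutants RPL -0.35 to 0.17, and in wild types ACT2 -0.11 to 0.73, YAB3 -0.47 to 0.81. In lec2-1 they were ALC -3.32 to 5.11, CP1 -1.31 to 6.25, DIN10 -1.08 to 0.29, FIL -0.51 to 1.2, GOLS2 -1.11 to 0.55 (-1.18 without its library of 15 and 17 DAF), RPL -0.09 to 0.64, SNRK2.6 -0.12 to 2.66 (2.86 without that library), YAB3 -0.15 to 0.87. Those of abi3-1 were ACT8 -0.66 to 0.07, APX1 -1.44 to 0.97, AT1G54410 -1.69 to 0.30, AT5G44310 -1.06 to 1.47, CDKB2;1 -0.27 to 3.94, CP1 -0.76 to 5.35, DREB2D -0.37 to 0.29, ETC1 -2.00 to 0.09, EXPA2 -0.04 to 4.54, FIL -1.83 to 0.03. Further ones there were GA20OX3 -2.91 to 0.17, GAPC1 -1.36 to 0.16, GL2 -0.67 to 0.16, HSFA9 -0.74 to 2.52, HSP101 -0.34 to 1.48, HSP18.2 -0.52 to 5.44, KNOLLE -5.29 to 1.26, MCM7 -4.58 to 0.17, MIPS1 -1.75 to 1.00, MUM2 -0.69 to 4.95. The rest were PDH-E1A -2.42 to 0.29, PKL -0.16 to 1.16, PKP1 -1.42 to 0.02, PLATZ1 -0.03 to 1.7, RBCS2B -4.62 to 0.07, RPL -0.81 to 0.34, SHP2 -0.07 to 0.50, SIP1 -2.39 to 0.14, SIP2 -0.43 to 0.90, TT4 -2.96 to 0.75, VTE1 -1.06 to 0.07. For the slope they were ABI2 -0.04 to 0.21, AHG1 -0.69 to 0.03, AS1 -0.04 to 0.61, AS2 -0.78 to 2.57, CRD -0.45 to 0.46, MCM7 -0.49 to 1.01, MUM4 -0.28 to 0.39, NOL -0.37 to 0.07, NYE1 -0.74 to 0.09. They also included OLEO1 -0.14 to 0.26, PCNA1 -0.19 to 1.48, PMEI6 -0.45 to 0.02, RPL -0.04 to 0.25, SIP2 -0.81 to 0.10, TTG2 -0.22 to 2.88, UBC21 -0.03 to 0.48, VCL41 -0.01 to 0.93, VCL43 -0.18 to 0.53.

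With library totals the counts were 6561 in lec1-1, 757 in lec2-1, 8029 in abi3-5, 0 in abi3-1, 5903 in fus3-3, 5461 for intolerant against tolerant mutants, and 40 lower and 3324 higher in the core. The median of all genes moved to 1.21 in lec1-1, and to 0.00 when the 100 most abundant genes were left out of the totals, so a few genes taking most of the counts may explain this shift. With DESeq2 the counts were 1952 in abi3-5, 2 in abi3-1, 619 for wild types, 12 for the slope and 607 higher in the core, and without the filter 1 for the slope. Without the day in the model they were 105 in lec2-1, 716 in abi3-5, 1863 in fus3-3 and 127 lower and 197 higher in the core. With a day effect per ecotype they were 0 in abi3-1, 1963 in fus3-3 and 253 higher in the core. With each ecotype fitted alone, which has fewer libraries, they were 565 in lec2-1, 822 in abi3-5, 0 in abi3-1, 114 in fus3-3 and 7 and 48 in the core. With lec1-1 against lec2-1 only, again fewer libraries, they were 204 and 44 and 42, and with both lec2-1 columns kept 458 in lec2-1. With the Col-0 days exchanged they were 1939 in abi3-5, 4060 for wild types, 458 for the slope and 392 lower in the core, and without these libraries, which leaves Col-0 with 1 library, 460 in fus3-3, 2972 for wild types, 27 for the slope and 90 and 111 in the core. Ws and Ler only gave 1915 for wild types. Of 142 list tests 56 were called by camera, 42 by fry and 0 with an estimated correlation.

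Leaving out 1 library or 1 day gave 867 to 2775 genes in lec1-1, 30 to 79 in lec2-1 (57 without its library of 15 and 17 DAF), 285 to 1501 in abi3-5, 0 to 1 in abi3-1, 1028 to 3089 in fus3-3, 847 to 2916 for intolerant against tolerant mutants (847 without the lec2-1 library of 15 and 17 DAF, 937 to 2045 without 1 day), 0 to 1744 for wild types, 0 to 17 for the slope, 20 to 315 lower in the core (172 without that library) and 64 to 406 higher (210). The wild type comparison has no value without day 15 or 21, and DESeq2 has no list test.

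With 10 splits of 3 against 3 libraries a share under 0.05 cannot be reached. As many genes as in the real split came from 1 of 10 in lec1-1 (3808, highest other 0), 1 in abi3-5 (1285, 0), 2 in abi3-1 (1, 2), 1 in fus3-3 (3057, 346, the last with fus3-3 at 15 and 17 DAF beside Col-0 at 17 DAF, and 1 among splits that part as many days), 10 for wild types by edgeR (0, 0) and 10 for the slope (0, 1). Of 100 regroupings drawn, 1 reached 2726 genes for intolerant against tolerant mutants, the real one (highest other 1294), 1 reached the 261 lower genes of the core and 1 the 380 higher (highest other 0 for both). The other regroupings mix libraries of 2 genotypes within a group, which widens its spread and leaves few calls. They therefore cannot exclude chance for these counts.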

Other observations

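The tests of a hold at 15 DAF below were chosen after the results were seen. In all 3 intolerant mutants the inositol phosphate synthase gene MIPS2 fell, by a log2 fold change of -2.38 (SE 0.47) in lec1-1, -1.90 (SE 0.47) in abi3-5 and -2.58 (SE 0.48) in fus3-3, n = 3 libraries per genotype. With library totals 0 genes of its list were called lower in lec1-1, so its call ended there. The phosphatase gene AHG1 of ABA signalling stood at -2.37 (SE 0.52), -1.85 (SE 0.52) and -1.72 (SE 0.52), and the endosperm gene EPR1, the only member of its list tested, at -2.43 (SE 0.55), -2.07 (SE 0.54) and -2.50 (SE 0.55). With library totals 0, 1 and 2 ABA genes were called lower in these mutants, so the call of AHG1 ended in lec1-1. Its call in the contrast of intolerant and tolerant mutants ended there too (-1.16, adjusted p = 0.0576, edgeR). The epidermis regulator GL2 rose by 3.50 (SE 0.56) in lec1-1 and by 1.89 (SE 0.53) in fus3-3.

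Lists not described above for lec1-1 were not called by camera: raffinose and inositol genes (3 of 9 lower), ABA genes (4 of 24 lower, 2 higher), antioxidants (4 of 15 lower, 2 higher), germination (3 of 14 higher, 1 lower), oil synthesis (2 of 21 lower, 1 higher), heat shock proteins (0 of 17), shoot apex (1 of 6 higher) and flavonoid genes (2 of 10 higher). With library totals 1 raffinose, 5 ABA, 3 antioxidant and 9 oil synthesis genes were higher there and 0, 0, 1 and 0 lower. In abi3-5 cell cycle genes rose in 1 of 12 cases (6 adjusted over the list alone, median 2.88, or 2.31 with absent genes at their bound, camera adjusted p = 0.000899, and adjusted p = 0.378 with an estimated correlation). Its transcription factors fell in 3 of 17 cases (median -0.88, and 0.53 with library totals, camera adjusted p = 0.026, and adjusted p = 0.352 with an estimated correlation). Raffinose and inositol genes fell there in 3 of 9 cases (median -0.55, and 1.00 with library totals, camera adjusted p = 0.026, and adjusted p = 0.283 with an estimated correlation), and antioxidants in 1 of 15 (median -0.36, and 1.1 with library totals, camera adjusted p = 0.0467, and adjusted p = 0.352 with an estimated correlation). With library totals 10 cell cycle, 6 transcription factor, 5 antioxidant and 1 raffinose gene were higher in abi3-5 and 0, 1, 1 and 2 lower, and with the Col-0 days exchanged 3 cell cycle genes were higher and 6 antioxidant genes lower. Seed coat mucilage genes were called in 2 of 8 cases in lec1-1 and 2 in fus3-3, 1 each way, and 0 in abi3-5. Of the 3 silique wall genes 1 rose in lec1-1. Of 9 reference genes 3 rose and 2 fell in lec1-1, 1 rose in abi3-5 and 2 in fus3-3, among them ACT2.

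A further hypothesis was that the intolerant mutants are held at the state of wild type seeds at 15 DAF. Oil and fatty acid synthesis genes, which fall from 15 to 21 DAF in Ws and Ler, would then be higher than in the wild type, but in fus3-3 their median was -1.08 after TMM scaling, and 0.22 with library totals, where the median of all genes was 1.14. In lec1-1 and abi3-5 it was 0.07 and -0.24 after TMM scaling. With library totals it was 1.29 and 1.34 there, where the median of all genes was 1.21 and 1.49. Storage protein genes fall over these days in Ws and Ler too and would be higher under a hold, but their medians were -2.94 in lec1-1, -3.33 in abi3-5 and -3.05 in fus3-3, and with library totals none was above -1.66, which argues against a hold of the whole seed state in all 3 mutants. A hold of photosynthesis genes alone was not tested.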
